A study of Homo sapiens with 12 samples.

How the data were processed

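The series holds 12 libraries of poly(A) RNA from HMC3 cells, in 4 groups of 3, assigned from the sample titles: input and IP of cells with a hairpin against METTL14, and input and IP of control cells. Per the labels' protocols, poly(A) RNA was fragmented, enriched with an m6A antibody, made into strand-marked libraries and sequenced as paired ends. The submitters' processing notes name fastp 0.19.4, HISAT2 2.0.4, StringTie 2.1.2, edgeR 4.1, HOMER 4.10 and GRCh38, with no role or order. The peak caller, the annotation and the test behind the peak p-values are not given in the sources used here.

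The authors deposited a table of FPKM values (fragments per kilobase and per 1e6 fragments, per the file headers) for 30161 genes in the 6 input libraries. Its column names carry a C for 3 libraries and a 3 for the others. The first were taken as control because C is the first letter of that label, and the others as shMETTL14 by elimination, with the library number in the name. This mapping is an inference from names, and METTL14's level was reported as a check of it. The authors also deposited 1 peak list per condition, with a log2 ratio of IP over input, a p-value and an adjusted p-value per peak, per the file headers. Tested on the values, both lists hold only peaks above 0 on that log2 scale with p under 0.05. The authors' differential table gives 8799 peaks with a log2 ratio for each condition, their difference and a p-value. All listed p-values are under 0.05, and 3 peaks have none. The authors' enrichment table gives gene numbers and an unadjusted p-value per term, per the file headers. A peak's log2 ratio is the authors' own value and was used to describe, filter and match peaks. Peak starts were deposited as 0-based: in the shNC list 4700 of them lay 1 base before the start of their gene in the expression table and 0 at it, while 2927 ends lay at the gene's end. Starts are given here 1-based on GRCh38, and a peak's span can include introns.

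No FPKM value of an IP library was in the table used here, so the planned comparison of IP over input per gene was not run, and neither was the fit over all 12 libraries. With no counts, no count test was run. No genome was used, so the DRACH motif was not searched. Gene names are those of the files. Of 719 entries in 30 gene lists, 681 matched by name, 2 through the symbols and synonyms of the GRCh38.p14 RefSeq gene table, and 36 were not matched.

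Genes with at least 1 FPKM in at least 3 of the 6 input libraries were kept (11684 genes). Values were tested as log2(FPKM + 1) without further scaling by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A change on the log2(FPKM + 1) scale understates the change of genes with low values. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the 30 lists. Gene ontology terms of 10 to 500 tested genes (1747 terms) were tested one-sided in each direction by the hypergeometric distribution, with adjustment over both directions. Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 base on the same strand. Expression calls and differential peaks were compared by Fisher's exact test (scipy 1.17.1), and genes with and without a peak by a permutation test of the difference in medians. Intervals of shares are 95% Wilson intervals and cover counting error only.

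On data simulated from the 11684 genes of the input comparison, limma recovered 61.25% of genes changed 1.5-fold, 82.5% of those changed 2-fold and 95.0% of those changed 4-fold, and 8.38% of its calls were false. Genes were drawn independently of each other there and few were changed, so these shares need not hold for the measured libraries. In a separate simulation, with genes drawn independently of each other, camera found the 1 list that was shifted and called none of the others. It cannot show how often the preset correlation gives false calls for lists of correlated genes. The overlap, Fisher and permutation steps recovered all 6 planted answers.

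The groups, main tests, 30 gene lists, alternatives and the naming rule were fixed before the data were examined. Exceptions are 4 alternatives chosen after seeing the data: single libraries left out, quantile normalization and median scaling for the gene lists, and a wider gene set for the Fisher tests. The tests that weigh explanations of the peak directions, the count of other splits, and the list of YAP and TAZ targets with its test were also chosen after results were seen. Genes were named if they were METTL14, MXD1 or another member of the lists of m6A machinery, or among the 10 highest or 10 lowest log2 changes past the threshold with non-overlapping groups and a mean of at least 2 FPKM in the higher group. Up to 3 called members with the smallest adjusted p were named per list. For peaks, those on MXD1 and METTL14 and the 5 highest and 5 lowest differences with a mean input of at least 1 FPKM were named. Not every gene that the rule selects is described. BHLHE40, SLX1B, MYC and the YAP and TAZ targets ANKRD1, F3, IGFBP3 and CCDC80 were named outside this rule after their values were seen. Alternatives covered the pseudocount, the filter, scaling, robust variance, the replicate number as a block, each library left out, thresholds for peaks and overlaps, and other list tests.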

Results

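RNA of HMC3 cells, a human microglial cell line, was profiled by RNA-seq and by m6A immunoprecipitation followed by sequencing (MeRIP-seq). In MeRIP-seq, fragmented poly(A) RNA is enriched with an antibody against N6-methyladenosine (m6A), and the immunoprecipitated fragments (IP) are set against the unenriched input. Cells carrying a short hairpin RNA against METTL14 (shMETTL14) were compared with cells carrying a control hairpin (shNC), both under hypoxia according to the series design. The sample titles call the first group a knock-out. METTL14 is the RNA-binding partner of METTL3 in the complex that writes m6A on mRNA. Each of the 4 groups (input and IP of both conditions) held 3 libraries. Expression values were used for the 6 input libraries, and the IP libraries entered only through the authors' peak tables. FPKM values summed to between 179866 and 187576 per input library. Read depth was not given. The most frequent of the low FPKM values, held by 38 to 55 genes per library, differed by at most 1.08-fold between libraries. Taken as a rough guide to depth, this gives close relative depths. Correlations of log2(FPKM + 1) between input libraries lay between 0.983 and 0.992. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

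The first question was whether the targeted mRNA was lower. METTL14 (chromosome 4, 118685392 to 118715433, GRCh38) stood at 4.01, 3.93 and 3.85 FPKM in shNC and at 1.55, 2.37 and 2.26 FPKM in shMETTL14. Its mean was 3.93 ± 0.0767 FPKM (SD, n = 3) in shNC and 2.06 ± 0.448 FPKM (SD, n = 3) in shMETTL14, a ratio of 0.524. It fell by 0.70 on the log2(FPKM + 1) scale (SE 0.11, limma adjusted p = 0.0172). Without shNC replicate 1, 2 or 3, the adjusted p was 0.0667, 0.0682 and 0.0533, and METTL14 was below every shNC library in all 3 shMETTL14 libraries. Of 9 m6A writer genes, METTL14 was lower and RBM15B, which guides the METTL3 complex to its targets, was higher. RBM15B rose from 8.88 ± 0.126 to 12.01 ± 0.278 FPKM (SD, n = 3, log2 change 0.40, limma adjusted p = 0.00773). METTL3, the catalytic subunit, was 4.01 ± 0.604 FPKM in shNC and 4.29 ± 0.211 FPKM in shMETTL14 (SD, n = 3, limma adjusted p = 0.605). WTAP, VIRMA, RBM15, ZC3H13, CBLL1 and METTL16 did not pass the threshold. Among 16 genes for m6A erasers and readers, IGF2BP1, a reader that stabilises bound mRNAs, rose from 13.4 ± 0.819 to 16.4 ± 0.405 FPKM (SD, n = 3, limma adjusted p = 0.0350). That call was lost when any 1 library was left out (adjusted p from 0.0688 to 0.11). The demethylases FTO and ALKBH5, the YTH-domain readers and the 8 remaining readers were not called.

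**Figure D1:**
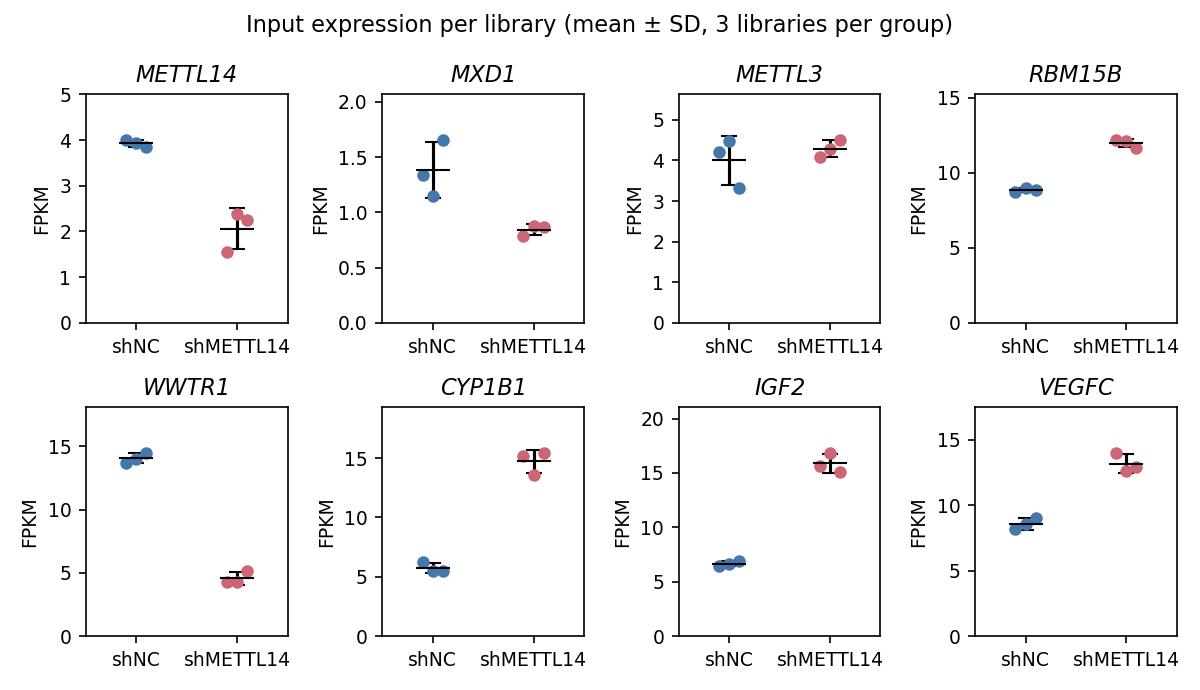
FPKM of 8 named genes in the 6 input libraries. Points are libraries, and black marks give the mean and SD of 3 libraries per group; METTL14 and WWTR1 lay lower and CYP1B1, IGF2 and VEGFC higher in every shMETTL14 library.

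MXD1, a MAX-binding repressor that opposes MYC, is the mRNA named in the study's title. MXD1 (chromosome 2, 69897688 to 69942945) had a mean of 1.38 ± 0.255 FPKM in shNC and 0.842 ± 0.0491 FPKM in shMETTL14 (SD, n = 3), a ratio of 0.609. All 3 shMETTL14 values lay below all 3 shNC values. The difference of -0.37 on the log2(FPKM + 1) scale (SE 0.092) had an unadjusted limma p of 0.00481 and an adjusted p of 0.0629, which misses the threshold of 0.05. In the 10 tested genes of the MYC, MAX and MXD network none was called (2 lower adjusted over the list alone), and MYC itself was 13.8 ± 0.760 FPKM in shNC and 13.4 ± 0.508 FPKM in shMETTL14 (SD, n = 3).

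Across the 11684 genes tested, 695 were called between the conditions, 402 higher and 293 lower in shMETTL14 (limma, adjusted p under 0.05). Neither the number nor the balance was stable: 299 were higher and 317 lower with quantile normalization, 431 and 222 at a minimum of 5 FPKM, 97 and 114 with the replicate number as a block, and 129 to 400 were called with 1 library left out. Most changes were small, and 4 of the higher and 7 of the lower genes changed by at least 2-fold on the log2(FPKM + 1) scale. Among genes meeting the naming rule, the highest changes were in RARRES2, which encodes the chemoattractant chemerin, in CYP1B1, a cytochrome P450 enzyme, and in IGF2, a growth factor. RARRES2 was 0.723 ± 0.186 FPKM in shNC and 3.32 ± 0.433 FPKM in shMETTL14 (SD, n = 3, log2 change 1.33, limma adjusted p = 0.00204). CYP1B1 rose from 5.75 ± 0.418 to 14.7 ± 0.983 FPKM and IGF2 from 6.65 ± 0.214 to 15.9 ± 0.871 FPKM (SD, n = 3). The taurine transporter SLC6A6 was 1.95 times as high in shMETTL14, and SHISAL1 2.19 times. The secreted protease HTRA1 also rose, by 0.78 on the log2 scale. The acute-phase genes SAA1 (log2 change 0.87) and SAA2 (0.78) and the nuclease gene SLX1A (0.77) rose as well, but each has a near-identical copy with which reads may be shared. SLX1A lost its call when any 1 library except shMETTL14 replicate 2 was left out (adjusted p up to 0.10), and its copy SLX1B had a log2 change of -0.23 (adjusted p = 0.0699).

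WWTR1, which encodes the transcriptional coactivator TAZ, fell most among protein-coding genes named here, from 14.1 ± 0.386 to 4.56 ± 0.499 FPKM (SD, n = 3), a ratio of 0.325 (log2 change -1.44, SE 0.071, limma adjusted p = 0.000384). The antisense RNA HIF1A-AS3 had the lowest log2 change among genes meeting the naming rule, -2.01, from 15.2 ± 2.33 to 3.02 ± 0.320 FPKM (SD, n = 3). It lies opposite HIF1A, and whether the authors counted by strand was not given, so its reads and those of HIF1A cannot be told apart with certainty. KISS1, the kisspeptin precursor, fell to a ratio of 0.453, BICD2, a dynein adaptor, to 0.473, and KRT8, an intermediate filament keratin, to 0.535. SNAPC1, TMEM40 and the phosphatase gene DUSP5 fell by 0.85, 0.82 and 0.82 on the log2 scale. KISS1 lost its call without shNC replicate 1 or 2 or shMETTL14 replicate 3 (adjusted p 0.0543, 0.0567 and 0.0579). DUSP5 lost it without shNC replicate 1 or any 1 shMETTL14 library (adjusted p from 0.0701 to 0.0953). The pseudogenes OR7E38P (log2 change -1.16) and RNU6-33P (-1.11) were also among the 10 lowest by that rule and may share reads with their relatives. OR7E38P lost its call when any 1 library was left out (adjusted p from 0.0741 to 0.118).

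Genes of cholesterol and fatty acid synthesis were lower together in shMETTL14 by camera with a preset correlation of 0.01 (median log2 change -0.26, adjusted p = 2.48e-09), but not with an estimated correlation (adjusted p = 0.284). Of 24 measured members, 8 fell, none rose and 16 were not called, and 16 were lower when adjusted over the list alone. Among the called members, MVD had a ratio of 0.797 and FDFT1, squalene synthase, a ratio of 0.805. With 1 library left out, 7 members were called lower without shMETTL14 replicate 2, 2 without shMETTL14 replicate 1 and 1 in each other case, while the list's median stayed between -0.29 and -0.23. FDFT1 lost its call when any 1 library was left out (adjusted p from 0.0508 to 0.10), and MVD when any except shMETTL14 replicate 2 was (up to 0.101). The p53 targets were lower by camera (24 measured, 1 fell, 1 adjusted over the list alone, median -0.13, adjusted p = 0.00458, and 0.540 with an estimated correlation). Their called member was MDM2, the p53 ligase, with a ratio of 0.762, which lost its call without any 1 shNC library or shMETTL14 replicate 3 (adjusted p from 0.0658 to 0.0994). Without shNC replicate 3 the list's adjusted p was 0.0522. The ATF4 and unfolded protein response list had a median of -0.19 with none of 25 members called in either adjustment (camera adjusted p = 0.00846, and 0.736 with an estimated correlation). Its adjusted p was 0.509 and its median -0.024 without shNC replicate 3, whose list median lay 0.33 above the mean of the libraries, and 0.0526 without shMETTL14 replicate 3. Of 16 matrix proteases and inhibitors, ADAMTS1 alone fell (ratio 0.719; 2 fell adjusted over the list alone; camera adjusted p = 0.0322, and 0.339 with an estimated correlation). That list's adjusted p was 0.0802, 0.0538 and 0.139 without shNC replicate 2, shNC replicate 3 and shMETTL14 replicate 3. Only 3 epithelial genes were measured, of which KRT8 and KRT18 fell (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0322, and 0.340 with an estimated correlation). Its adjusted p was 0.0570, 0.0565 and 0.0533 without shNC replicate 3, shMETTL14 replicate 2 and shMETTL14 replicate 3.

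NF-kB target genes were higher together by camera with the preset correlation, but not with an estimated correlation. Of 17 measured, 8 rose and none fell (15 higher and 1 lower adjusted over the list alone, median 0.29, camera adjusted p = 7.74e-07, and 0.284 with an estimated correlation). The inhibitor NFKBIA rose from 15.8 ± 0.607 to 24.1 ± 0.601 FPKM, the chemokine CXCL3 from 1.65 ± 0.267 to 3.44 ± 0.140 FPKM, and NFKB2 from 6.98 ± 0.19 to 9.04 ± 0.283 FPKM (SD, n = 3). With 1 library left out, 2 to 6 of the 17 were called. NFKB2 lost its call without any 1 shNC library or shMETTL14 replicate 3 (adjusted p from 0.0507 to 0.0698). Genes of G2/M and mitosis were also higher, with 10 of 30 called higher and none lower (15 higher adjusted over the list alone, median 0.22, camera adjusted p = 7.74e-07, and 0.284 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, had a ratio of 1.28, the mitotic kinase PLK1 1.31 and UBE2C 1.26. Of the 30 genes, none was called without shNC replicate 1, 2 without shNC replicate 2, 3 without shMETTL14 replicate 3, and 5, 6 and 10 without shNC replicate 3, shMETTL14 replicate 1 and shMETTL14 replicate 2. CDC20, PLK1 and UBE2C lost the call without shNC replicate 1 (adjusted p 0.0522, 0.0540 and 0.0506), and PLK1 and UBE2C also without shNC replicate 2 (0.0505 and 0.0567). Of 30 G1/S and S-phase genes, 2 rose in either adjustment, MCM7 (ratio 1.26) and RRM2 (1.20), with a camera adjusted p of 0.0245 (0.442 with an estimated correlation). MCM7 lost its call without shNC replicate 2 (adjusted p = 0.0533), and RRM2 when any 1 library except shMETTL14 replicate 2 was left out (up to 0.134). The G1/S list lost its call with quantile normalization (adjusted p = 0.10) and without shNC replicate 3 or shMETTL14 replicate 3 (0.0538 and 0.0526). MYC targets had a median of 0.066, with 2 of 28 higher in either adjustment, PPAN and RRS1 (camera adjusted p = 0.0191, 0.284 with an estimated correlation, and 0.138 with quantile normalization). Both genes lost their calls when any 1 library was left out (adjusted p up to 0.107 for PPAN and 0.138 for RRS1).

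Of 11 measured replication-dependent histone genes, 2 rose, H2BC11 (ratio 1.67) and H2BC5 (1.42), and 5 adjusted over the list alone (median 0.26, camera adjusted p = 0.00216, and 0.368 with an estimated correlation). H2BC11 lost its call without shNC replicate 1 or 2 or shMETTL14 replicate 1 (adjusted p up to 0.0646), and H2BC5 without these or shMETTL14 replicate 3 (up to 0.0959). Histone genes are close copies of each other, and only 11 of the 42 listed passed the expression filter in this poly(A) RNA, so these levels are uncertain. The mesenchymal and pericyte list had 4 of 12 members higher and 1 lower (9 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.00216, and 0.351 with an estimated correlation). THY1 rose from 39.4 ± 0.872 to 54.7 ± 0.981 FPKM and MYL9 had a ratio of 1.21, while the actin-binding CNN1 fell to a ratio of 0.541. With any 1 library left out, 1 member was called higher and 1 lower. MYL9 lost its call when any 1 library was left out (adjusted p from 0.0519 to 0.0861). Interferon-stimulated genes had a median of 0.40 with none of 33 called in either adjustment (camera adjusted p = 0.000411, and 0.736 with an estimated correlation). The list's median lay 0.60 above the mean of the libraries in shMETTL14 replicate 2 and 0.39 below it in shNC replicate 2 (deviation -0.39), and without shMETTL14 replicate 2 its median was 0.15 and its adjusted p 0.0478. Without shNC replicate 2 the median was 0.28. The 42 cytosolic ribosomal protein genes had a median of 0.057 and no called member in either adjustment (camera adjusted p = 0.0245, and 0.793 with an estimated correlation). With quantile normalization the ribosomal direction turned (median -0.0058, adjusted p = 0.735), and its adjusted p was 0.410, 0.318 and 0.214 without shNC replicate 1, shMETTL14 replicate 1 and shMETTL14 replicate 3.

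**Figure D2:**
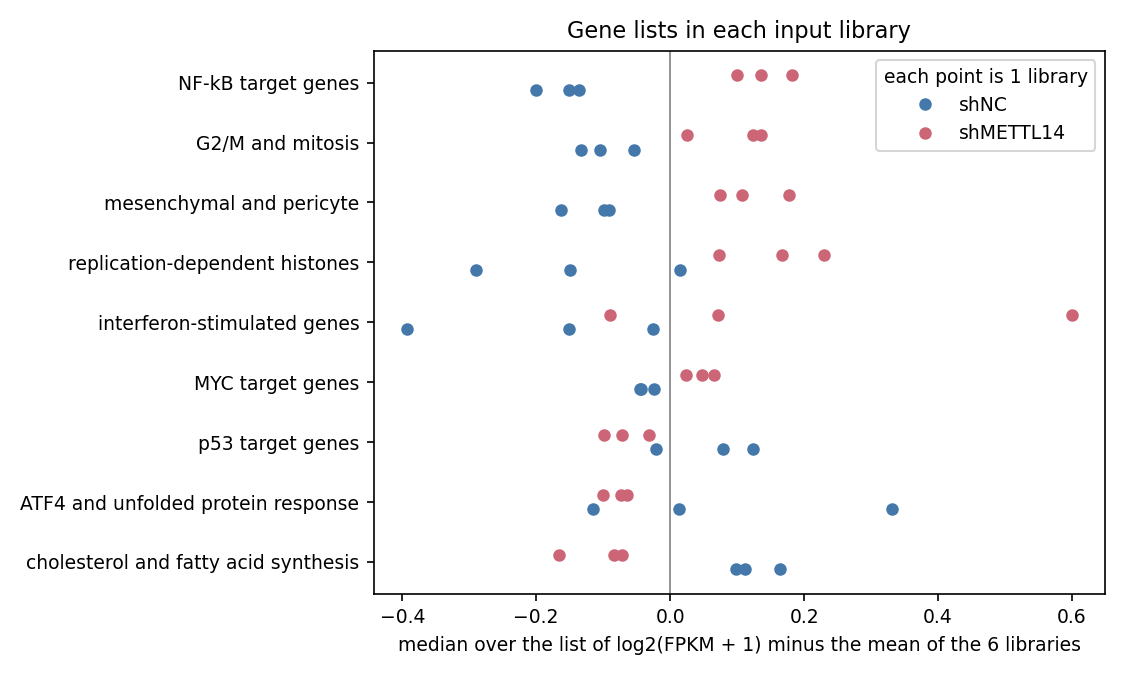
Median deviation of 9 gene lists in each of the 6 input libraries, on the log2(FPKM + 1) scale relative to the mean of the 6 libraries. Each point is 1 library; NF-kB targets lay higher and cholesterol and fatty acid synthesis lower in all 3 shMETTL14 libraries, while interferon-stimulated genes stood at 0.60 in shMETTL14 replicate 2.

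The other 17 lists were not called by camera (adjusted p from 0.0826 to 0.875). Of 23 measured angiogenic factors, 4 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.718), with a median of -0.028, a mean of 0.059 and a test direction upward. With 1 library left out, 1 to 3 were called higher and 1 or 2 lower. VEGFC, a lymphangiogenic growth factor, rose from 8.57 ± 0.427 to 13.2 ± 0.726 FPKM, whereas CCN2 fell from 58.0 ± 6.06 to 36.9 ± 0.349 FPKM and FGF1 from 2.52 ± 0.168 to 1.57 ± 0.109 FPKM (SD, n = 3). FGF1 lost its call without any 1 shNC library or shMETTL14 replicate 3 (adjusted p up to 0.0677). Of 26 hypoxia-inducible factor targets, TFRC rose and NDRG1, LOX and BHLHE40 fell (3 higher and 5 lower adjusted over the list alone, adjusted p = 0.0837, and 0.0310 without shNC replicate 1). NDRG1 had a ratio of 0.487 and LOX 0.729. NDRG1 lost its call without shNC replicate 2 or 3 or shMETTL14 replicate 3 (adjusted p up to 0.0642), LOX when any except shMETTL14 replicate 2 was left out (up to 0.0836) and TFRC when any except shMETTL14 replicate 1 was (up to 0.101). In glycolysis, the lactate exporter SLC16A3 rose (ratio 1.28) and HK2 fell (0.741; 3 higher and 1 lower adjusted over the list alone), with an adjusted p of 0.250 for the list, whose median turned negative with quantile normalization (-0.0065). SLC16A3 lost its call without any 1 shNC library (adjusted p up to 0.0682), and HK2 when any except shMETTL14 replicate 2 was left out (up to 0.0807). The TGF-beta and matrix list had 1 member higher, SMAD7, and 4 lower (2 higher and 5 lower adjusted over the list alone, adjusted p = 0.278), with a median of 0.012 against a mean of -0.042. With 1 library left out, at most 1 was called higher and 1 to 3 lower. SMAD7 lost its call without shNC replicate 1 or 2 or shMETTL14 replicate 1 or 3 (adjusted p up to 0.0773). Of 19 immediate early genes, FOSL1 (ratio 1.57), KLF6 (1.23) and JUNB (1.29) rose and DUSP5 fell (5 higher and 4 lower adjusted over the list alone). In this list 12 of 19 changes were negative, with a median of -0.096 and an adjusted p of 0.715. KLF6 lost its call when any 1 library except shMETTL14 replicate 1 was left out (adjusted p up to 0.0871), and JUNB when any except shNC replicate 3 was (up to 0.122). The microglia lists were thinly measured: 5 of 25 identity genes, 8 of 26 pro-inflammatory and 5 of 18 anti-inflammatory genes passed the expression filter, with adjusted p of 0.115, 0.0826 and 0.740. No identity or anti-inflammatory gene was called (2 and 1 lower adjusted over the list alone). The pro-inflammatory list had 5 members higher and 1 lower adjusted over the list alone, and 1 called member, CCL2 (ratio 1.59, call lost when any 1 library except shMETTL14 replicate 2 was left out, adjusted p up to 0.0721), and an adjusted p of 0.0436 without shMETTL14 replicate 1. Markers of endothelium, and of astrocytes and neurons, had 2 and 3 measured genes with none called (adjusted p = 0.250 and 0.760). The 13 mitochondrially encoded genes had no called member (adjusted p = 0.0826, and 0.00158 and 0.000273 without shNC replicate 1 and shMETTL14 replicate 3). They made up at most 0.0334% of the FPKM sum in any library, and copies in the nuclear genome leave these values uncertain. The lists of m6A writers, erasers and readers, known m6A-marked mRNAs, heat shock proteins, the MYC, MAX and MXD network and mRNA decay had adjusted p of 0.360, 0.760, 0.250, 0.715, 0.718 and 0.875. For anti-inflammatory genes, erasers and readers and mRNA decay the median (0.022, 0.0016 and 0.014) and the test differed in sign.

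Among gene ontology terms of the expression table, tested over 10253 tested genes with a term, 5 were enriched among the higher and 5 among the lower genes. Neutrophil chemotaxis held 6 of 16 tested genes among the higher calls against 0.599 expected (hypergeometric test, adjusted p = 0.0108), namely 5 CXCL chemokines and SAA1. Mitotic metaphase plate congression held 7 of 22 (adjusted p = 0.00895). Cornification held 7 of 18 tested genes among the lower calls (adjusted p = 0.000280), which were desmosome and keratin genes, and cell-cell adhesion held 8 of 47 (adjusted p = 0.0123). The same 5 CXCL chemokines were also in the enriched antimicrobial peptide term. DSC3, DSG2, DSP and KRT18 were in both cornification and cell-cell adhesion, so the terms are not separate results. The hypergeometric test treats genes as independent and rests on the 695 calls, whose number was not stable. The authors' deposited table of enriched terms lists 104 genes of the extracellular region, 25 of angiogenesis and 9 of chemokine activity among the genes the authors called changed, with an unadjusted p of 5.36e-14, 4.75e-08 and 2.54e-08. Of these 9, CCL2, CXCL3, CXCL5 and CXCL6 were called higher here and CCL26 lower (log2 change -0.77, limma adjusted p = 0.0343). CCL11 (-0.55, limma adjusted p = 0.0703) and CXCL8 (0.63, limma adjusted p = 0.0557) were not called. CCL20 and CCL5 did not pass the filter. Of 510 genes of the expression table with a name in that list, 232 passed the filter used here, and 59 were called higher and 106 lower. The rest of the 510 were not tested here. Of the 695 calls, 23.7% had a name in that list. That list was chosen by the authors on these libraries, so it is not independent evidence.

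The second assay asked where m6A-enriched fragments lay and how they changed. The authors' lists hold 43405 peaks on 16373 genes for shNC and 41425 peaks on 16216 genes for shMETTL14, each called over the libraries of the condition, so there is no replicate test of these numbers. Of the shNC peaks, 55.3% were annotated to 3′ UTRs, 14.6% to 5′ UTRs, 12.7% to coding exons, 12.4% to exons of non-coding RNA and 4.75% to introns. The shMETTL14 shares were 55.6%, 15.0%, 12.2%, 12.4% and 4.49%. At an overlap of at least 1 base on the same strand, 78.9% of shNC peaks and 82.1% of shMETTL14 peaks overlapped a peak of the other list. A peak was listed in both conditions for 15577 genes.

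Most differential peaks had a higher IP over input in shMETTL14. The authors' deposited table of differential peaks names its conditions only as treated and control. Its treated values matched the shNC list within 0.05 at 97.8% of 2025 identical intervals, and its control values matched the shMETTL14 list at all 1969, so differences are given here as shMETTL14 minus shNC. At the authors' adjusted p under 0.05, 3390 peaks differed, 2843 higher and 547 lower in shMETTL14. This is 83.9% higher (95% Wilson interval 82.6 to 85.1%, treating peaks as independent). The median difference was 0.27 log2 units for the higher and -0.73 for the lower peaks. Among peaks with at least a 2-fold difference, 302 were higher and 204 lower (59.7%). The share of higher peaks was 88.3% in 3′ UTRs, 78.8% in 5′ UTRs, 79.3% in coding exons, 72.9% in exons of non-coding RNA and 59.8% in introns.

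**Figure D3:**
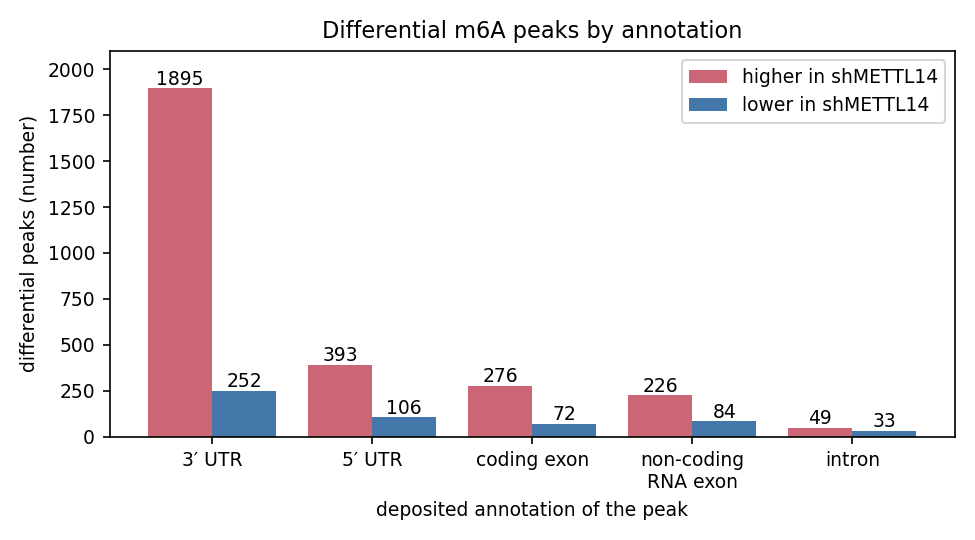
Number of differential peaks by the deposited annotation, split by direction (adjusted p under 0.05 in the authors' deposited table). Bars are peak counts; in 3′ UTRs 1895 peaks were higher and 252 lower in shMETTL14.

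In the authors' deposited table, 1 MXD1 peak was listed, at 69941560 to 69941684 on chromosome 2 in the 3′ UTR. Its log2 IP over input was 1.15 in shNC and -0.21 in shMETTL14, with a p of 0.0344 and an adjusted p of 0.187, which misses the threshold. The authors' peak lists hold 7 MXD1 peaks for shNC and 6 for shMETTL14, and that interval is covered by a peak in the shNC list alone. The log2 IP over input of these peaks ran from 0.32 to 1.53 in the authors' deposited table for shNC and from 0.45 to 1.79 in that for shMETTL14. Where peaks of the 2 lists overlapped, the shMETTL14 value was above the shNC value. In the 5′ UTR these were 0.45 against 0.32. In the 3′ UTR they were 1.29 against 1.23, 1.79 against 1.53, 1.07 and 0.91 against 0.68, and 1.70 against 0.82. The overlapping peaks differ in extent, and their values were not tested against each other. The median over all peaks was also higher in the shMETTL14 list (1.13 against 1.07). MXD1 input was lower in shMETTL14, which can by itself move IP over input, so a gain particular to MXD1 is not shown. An exonic shNC peak (0.74) and the shNC peak over the differential interval (0.92) overlapped no shMETTL14 peak. The strongest MXD1 peak of each list lay in the 3′ UTR, at 69940060 to 69940834 in shNC and at 69940035 to 69940959 in shMETTL14. None of the other MXD1 peaks is in the differential table, which keeps only peaks at p under 0.05, so the single interval does not speak for the m6A of the whole mRNA. On METTL14 the authors' deposited table has a peak at 118700569 to 118711570 on chromosome 4, higher in shMETTL14 (2.26 against 2.52, adjusted p = 0.0136). Its span includes introns and ends in the 3′ UTR. The authors' peak lists hold 5 METTL14 peaks for shNC and 1, in this place, for shMETTL14. The 4 peaks in the shNC list alone, 1 exonic and 3 in the 3′ UTR, had a log2 IP over input of 0.61 to 0.93 in the authors' deposited table. None is in the differential table, and METTL14 mRNA was lower in shMETTL14, so their absence from that list is not evidence of less m6A.

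**Figure D4:**
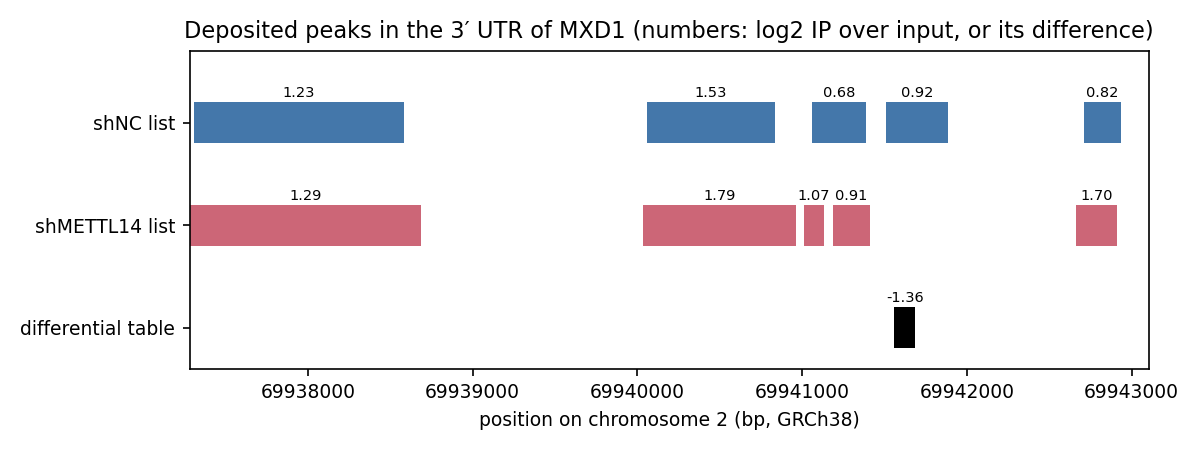
Deposited peaks in the 3′ UTR of MXD1 on chromosome 2 (GRCh38, base pairs), by list. Numbers give each peak's log2 IP over input, or in the bottom row the difference, shMETTL14 minus shNC; the interval with a difference of -1.36 lies under an shNC peak.

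The 5 highest differences among expressed genes in the authors' deposited table were in GSE1 (3.88 log2 units, intron), ZNF638 (3.77, 5′ UTR), FAM156A (3.38, 5′ UTR), TCAF1 (3.17, 3′ UTR) and SGMS1 (2.90, 3′ UTR). The 5 lowest in that table were in NOMO1 (-5.93, 5′ UTR), GOLGA8B (-5.82, coding exon), PKD1P1 (-4.25, non-coding exon), U2AF1L5 (-4.17, 5′ UTR) and TNRC6C (-3.90, 3′ UTR). NOMO1, GOLGA8B, PKD1P1, U2AF1L5 and FAM156A belong to families of near-identical copies, so their reads may be shared. None of these 10 genes was called in the input comparison.

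Called genes were compared with peaks at the authors' adjusted p under 0.05 among the 5408 tested genes that hold a peak in the differential table. That table keeps only peaks at p under 0.05, so this comparison is between genes with more and less certain m6A differences and says nothing on genes without a listed peak. Of 157 genes called lower, 79 had a peak that was higher in shMETTL14 against 64.9 expected (odds ratio 1.45, Fisher's exact test, two-sided, p = 0.0214, adjusted p = 0.0854 over 4 tests), and 8 had a lower peak against 12.3 expected (odds ratio 0.626, adjusted p = 0.337). Of 177 genes called higher, 79 had a higher peak against 73.2 expected (odds ratio 1.15, adjusted p = 0.393) and 18 a lower peak against 13.8 expected (odds ratio 1.35, adjusted p = 0.337). None passed the threshold, and 2 pairings passed it with expression at an unadjusted p under 0.05. These were lower expression with higher m6A (odds ratio 1.32, adjusted p = 0.00278) and higher expression with lower m6A (odds ratio 1.74, adjusted p = 7.38e-05). A wider set of 11039 tested genes with a peak in any of the authors' 3 peak tables was chosen after this result was seen. In it, 79 of 279 genes called lower had a higher peak against 56.5 expected (odds ratio 1.58, Fisher's exact test, adjusted p = 0.00449), and the other 3 pairings did not pass (adjusted p from 0.701 to 0.949). Expression levels were not matched in these comparisons, and because IP is divided by input, a change of input alone can move both measures.

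Genes with an m6A peak shifted slightly upward relative to those without. The 10887 tested genes with an shNC peak had a median log2 change of 0.015, and the 797 without had -0.0067. The difference in medians was 0.021 (two-sided permutation test across genes, 100000 resamples, p = 0.00159), and genes are not independent replicates. Genes with a peak had a higher median level (5.87 against 2.58 FPKM), and matched on mean expression the difference was 0.016 (permutation p = 0.0183). With peaks of either list it was 0.021 (permutation p = 0.00465), and with peaks of at least 4-fold enrichment 0.0046 (permutation p = 0.201).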

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

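The tests of IP recovery and of input expression in this part, and the count of other splits, were chosen after the results were seen. Both tests of the condition names were written before their results were seen, the second after the first did not decide. In the authors' differential table, IP over input differed between the conditions at 2843 peaks that were higher and 547 that were lower in shMETTL14, which stands out because METTL14 is part of the complex that writes m6A.

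An exchange of the condition names between the peak lists is argued against. The number of peaks per gene gave no answer, with a Spearman rho of 0.023 against the input change across 665 called genes (95% bootstrap interval -0.052 to 0.097). Standard errors of peaks were worked out from the deposited log2 value and p, and shrink as a transcript becomes more abundant. For peaks shared at a reciprocal overlap of 50%, their log2 ratio, shNC over shMETTL14, followed the input change. The rho was 0.826 across 543 called genes (0.790 to 0.857), the sign that correct names require. That test takes the inferred mapping of the expression columns as given. Input changes as the whole cause are also argued against, since 85.5% of differential peaks were higher in shMETTL14 among genes with an input log2 change between -0.1 and 0.1 (83.7 to 87.3%). A general difference in IP recovery or scaling stays open: each annotation class of at least 100 differential peaks had mostly higher peaks, the lowest share being 72.9% for exons of non-coding RNA, as such a difference may give. Introns, with fewer peaks, were outside that test. A biological effect of the knock-down on the distribution of m6A also stays open and untested, since IP over input is relative and no spike-in value was used here.

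The 695 genes called in the input comparison were set against the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 gave as many genes, the real one, and the highest of the others gave 3. With 10 splits no share under 0.05 is possible.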

How the results depend on the processing

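Leaving out single libraries and rescaling for the gene lists, and the wider gene set of the Fisher tests, were alternatives chosen after seeing the data. The 695 calls became 105 without a filter on low values, with 30161 genes tested, 211 with the replicate block (97 higher, 114 lower), and 129 (without shNC replicate 2) to 400 (without shMETTL14 replicate 2) with 1 library left out and fewer samples. All 695 kept their sign in each of these. The filter and the block leave a gene's log2 change itself unaltered, and the smaller fits reuse libraries that selected the 695. The kept signs are therefore no separate evidence. Library numbers did not pair the samples (correlations of deviations 0.0070, -0.0080 and -0.011). The share of higher calls was 57.8%, 48.5% with quantile normalization, 50.9% with scaling to 1 median and 66.0% at a minimum of 5 FPKM (653 called, 431 higher and 222 lower). The METTL14 change of -0.70 had an adjusted p of 0.0866 without a filter and ranged from -0.78 to -0.57 with 1 library left out. MXD1 stayed negative and above the threshold in every alternative that tested it (adjusted p 0.0581 to 0.187). Neither METTL14 nor MXD1 was tested at a minimum of 5 FPKM. Of the 30 lists, 13 were called, 0 with an estimated correlation, and 8 to 14 with 1 library left out, fewest without shNC replicate 3. Of the 13, 8 held without shNC replicate 3 or shMETTL14 replicate 3 and 12 without any other 1. The further calls were of lists not called with all libraries. With fry, another list test, 8 of the 13 kept the call (fry adjusted p from 0.00149 to 0.0365). Interferon-stimulated genes (0.338), the ATF4 list (0.502), p53 targets (0.167), ribosomal proteins (0.426) and histones (0.0519) lost it. Pro-inflammatory (0.0297) and microglia identity genes (0.0434), not called by camera, passed the threshold with fry.

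Peaks of at least 2-fold enrichment numbered 23591 in shNC and 24133 in shMETTL14, so that the order of the lists turned. The shared shares were 62.0% and 65.0% at a reciprocal overlap of 50%, and 82.1% and 80.3% at 2-fold enrichment. Differential peaks numbered 8796 at p under 0.05 (6627 higher), 1718 at a false discovery rate under 0.01 (1524 higher) and 506 at 2-fold (302 higher). With expression at unadjusted p under 0.05, the odds ratios were 1.32 (lower expression, higher m6A), 1.74 (higher, lower) and 0.860 (higher, higher, turned). With differential peaks at p under 0.05, the odds ratios were 1.91 (lower, higher, adjusted p = 0.0365) and 0.801 (higher, higher, turned). There every peak with a p-value counts as differing, so only the balance of directions is compared, and nothing is concluded from it. Over genes with a peak in any of the 3 tables, the odds ratio for lower expression and higher m6A was 1.58 (adjusted p = 0.00449). With 2-fold peaks, 3 turned below 1 (0.989, 0.960 and 0.336). The median difference of genes with a peak was 0.0046 (permutation p = 0.201) at 4-fold enrichment. The cause of these changes was not tested.

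Among named genes and lists, of which ribosomal proteins alone had been called, the sign turned with quantile normalization for YTHDF1 (-0.0095), and the direction of the test and the median for ribosomal proteins (-0.0058) and glycolysis (-0.0065). The median alone turned there for erasers and readers (-0.026), TGF-beta and matrix (-0.021) and mRNA decay (-0.019), and that of known m6A-marked mRNAs fell to 0. With fry the direction of the test, but not the median, turned upward for immediate early genes (median -0.096) and mRNA decay (0.014). With 1 library left out, the sign turned for METTL3 (-0.016 to 0.15), YTHDF3 (-0.057 to 0.024) and FMR1 (-0.16 to 0.0082). The direction of the test turned for heat shock proteins (medians -0.083 to 0.027) and immediate early genes (-0.12 to -0.0094) without shNC replicate 3, and for mRNA decay (-0.025 to 0.023) without shMETTL14 replicate 1 or 3. The medians of 5 other uncalled lists took both signs while their test kept its direction: angiogenic factors, TGF-beta and matrix, anti-inflammatory genes, erasers and readers, and the MYC, MAX and MXD network. Of the other values, with lists judged by the direction of their test, 1201 kept direction and side of the threshold, 225 lost and 8 gained the call. The comparison of IP over input per gene, the fit over 12 libraries and count tests were not run, because the table holds FPKM of input libraries. Absolute depth is unknown, which limits statements on genes near 1 FPKM, MXD1 included.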

Other observations

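The test in this part was chosen after the fall of WWTR1 was seen, on a list of 22 YAP and TAZ target genes written before the list's own result was known. CCN2, a member that had already been seen, also belongs to 2 of the other lists. WWTR1 encodes TAZ, and 1 hypothesis is that its target genes may be lower together in shMETTL14. Of 20 measured targets, 5 fell and none rose, and adjusted over the list alone 5 were lower and 2 higher. The called members were ANKRD1, CCN2, F3, IGFBP3 and CCDC80, named after their values were seen. Their log2 changes were -0.62, -0.63, -0.72, -0.49 and -0.27. The list's median was -0.080. The list was lower by camera with the preset correlation (p = 0.00801) and by fry (p = 0.0243). By camera with an estimated correlation it was not (p = 0.216). As the tests differ, the question cannot be decided with these libraries. In the authors' deposited table, WWTR1 has a 3′ UTR peak at 149520410 to 149520809 on chromosome 3 that was higher in shMETTL14 (0.56 against 0.83, adjusted p = 0.0375). So were 83.9% of all differential peaks, and the fall of WWTR1 input (ratio 0.325) can by itself move IP over input. The peak is therefore no evidence on why WWTR1 fell.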
